A study of Arabidopsis thaliana with 12 samples.

How the data were processed

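The deposited table held raw counts per gene, which the authors made, per the submitters' processing notes, by trimming reads with Trim Galore 0.3.3, aligning them to TAIR10 with TopHat2 2.1.0 and counting them with featureCounts of Subread 1.4.6. Libraries came from seedling RNA, TruSeq Stranded mRNA kits and 75 bp single-end reads on a NextSeq, per the labels. The strand setting of the counting was not given, so counts of overlapping or antisense genes are uncertain, and near-identical paralogs (LHCB1 genes, bHLH38 and its neighbours, plant defensins, glutathione S-transferases) may share reads. The table had 21543 loci and 12 libraries, each locus with at least 5 counts in at least 3 libraries, so genes near 0 in all groups were not analysed here, and neither were organelle genes. RefSeq TAIR10.1 matched 21519 loci and 24 stayed unmatched.

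Comparisons, gene lists and alternatives were chosen before the data were examined. Counts were fitted in edgeR 4.0.16 under R 4.3.3 with TMM scaling and a robust quasi-likelihood model with 1 mean per group, after filterByExpr (minimum count 10, minimum total 15), which removed 802 loci and left 20741. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The common biological coefficient of variation was 12.7%, the median prior degrees of freedom 3.58 and the prior count 0.125. Where a group had 0 counts, a fold is a lower bound with 3 counts over the group as the floor; where it had 1 to 3 counts, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only. The origin of the replicates was not stated, so p-values measure the spread between these samples.

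The 25 gene lists held 471 entries for 468 loci, of which 452 entries were in the table. The list of seed storage genes had 2 members there and 0 past the filter, and was not tested. Lists were tested with camera in limma 3.58.1 (voom weights, preset correlation 0.01), with camera at an estimated correlation and with fry. Response size was the median, over genes changed by methyl viologen on average, of the interaction signed by that average.

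Named genes followed a rule: for each pairwise comparison the 6 largest rises and 6 largest falls among called genes with a symbol, at least 1 CPM in the higher group and libraries that did not overlap between groups, which 10% of unchanged genes would show by chance in 3 against 3; for each list the 3 members with the smallest adjusted p, or the 2 most expressed where none passed; the 5 largest interactions of each sign; and always MED8 and the 5 ROS hallmark genes. Other list members named were chosen after their values were seen.

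Alternatives were RLE and upper-quartile scaling, no filter, 1 CPM in 3 libraries, a replicate block, DESeq2 1.42.0, fits of only the groups compared, and fits without each library. No label said what a replicate number marks, so the model had no block. A root marker covariate was added after the data were seen, as was leaving out 2 libraries together that stood apart from their groups. Chi-square per degree of freedom was 35.26 and 26.31 for Col-0 control replicate 1 against the other Col-0 controls (8.99 between those) and 34.72 and 37.4 for med8 control replicate 3 (6.4). Simulations, given with the results, held fewer changes: rates here may differ.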

Results

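The series profiled two-week-old Arabidopsis thaliana seedlings of Col-0 and of a med8 mutant, grown on control medium or on medium with 25 nM methyl viologen, the herbicide that passes electrons from photosystem I to oxygen and so forms superoxide. Each of the 4 groups had 3 libraries, and the libraries held between 30.47 and 34.69 M counts. Of 21543 loci in the table, 20741 passed the count filter and were tested with edgeR's quasi-likelihood test. In what follows, a value after a gene name is its log2 fold change ± SE, CPM values are means of 3 libraries ± SD where an SD is given, and a gene "rose" or "fell" where its Benjamini-Hochberg adjusted p was under 0.05. Gene lists fixed beforehand were tested as groups with camera at a preset correlation, and each call is given with its adjusted p under an estimated correlation. Where adjusting over the list alone gave other counts than adjusting over all genes, both are given. A range given with a lost or gained call is that of the adjusted p over all alternatives of that result.

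MED8 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. MED8 stood at 20.48, 20 and 18.87 CPM in the Col-0 control libraries and at 22.22, 19.41 and 20.15 CPM in Col-0 on methyl viologen. The med8 libraries held 5.06, 5.23 and 6.41 CPM on control medium and 6.21, 5.46 and 4.85 CPM on methyl viologen, which is 28.1% and 26.8% of Col-0. MED8 was lower in med8 on control medium (−1.83 ± 0.11, edgeR adjusted p = 5.51e-05) and on methyl viologen (−1.90 ± 0.11, edgeR adjusted p = 1.21e-06). Methyl viologen itself gave MED8 values of 0.06 ± 0.10 in Col-0 (edgeR adjusted p = 0.724) and −0.02 ± 0.12 in med8 (edgeR adjusted p = 0.927), with an interaction of −0.07 ± 0.16 (edgeR adjusted p = 0.829).

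In Col-0, methyl viologen raised genes of iron shortage, anthocyanin synthesis, detoxification and the mitochondrial stress response, and lowered nuclear photosynthesis genes and ferritins. The largest rises included the alternative NADH dehydrogenase gene NDB4 (127-fold, 0.0649 to 8.64 CPM), the Nudix hydrolase gene NUDT24 (80.2-fold), the late embryogenesis gene LEA7 (70.1-fold, to 14.5 ± 7.78 CPM), the anthocyanin gene DFR (43.6-fold) and the iron shortage regulator BHLH100 (40.4-fold, 6.05 to 245 CPM). A further alternative dehydrogenase gene, NDB3, had 1 count in the Col-0 controls and 2.8 CPM on methyl viologen, a ratio of 265 (counting interval 47.1 to 10500). Among the largest falls were the cytochrome P450 genes CYP93D1 (52.6-fold, 3.66 to 0.0662 CPM) and CYP76G1 (26-fold), the iron-sulfur protein gene NEET (31.6-fold, 38.4 to 1.22 CPM), PCC1 (11.3-fold, 133 to 11.8 CPM) and ENH1 (10.7-fold, 99.5 to 9.27 CPM).

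Of 21 iron deficiency genes tested in Col-0, 16 rose with methyl viologen and none fell (19 rose over the list alone), with a median of 2.113. IMA3, a small peptide that signals iron shortage, rose from 7.11 to 72.8 CPM (3.36 ± 0.13), BHLH101 from 3.9 to 47.1 CPM (3.59 ± 0.16) and the regulator PYE from 11.3 to 41.2 CPM (1.87 ± 0.08; edgeR adjusted p at most 3.15e-07 for these). FIT, the regulator of root iron uptake, had −0.37 ± 0.24 (edgeR adjusted p = 0.273), whereas its target IRT1, the root iron transporter, rose (1.61 ± 0.38, edgeR adjusted p = 0.00828). The iron list passed camera (camera adjusted p = 1.13e-15, or adjusted p = 0.0932 with an estimated correlation). Ferritins, which store iron, went the other way: 3 of 4 fell and none rose (median −1.815, camera adjusted p = 0.00121, or adjusted p = 0.0932 with an estimated correlation). FER4 fell from 35.6 to 3.49 CPM (−3.35 ± 0.17), FER1 from 77.9 ± 42.5 to 12.3 CPM (−2.66 ± 0.32) and FER3 from 45 to 22.9 CPM (−0.97 ± 0.13; edgeR adjusted p at most 0.000212 for the ferritins that fell).

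All but 2 of the 17 genes of the mitochondrial dysfunction response rose in Col-0 and none fell (median 1.881, camera adjusted p = 2.29e-14, or adjusted p = 0.0963 with an estimated correlation). UPOX rose from 3.53 to 36.2 CPM (3.36 ± 0.16), the glucosyltransferase gene UGT74E2 from 3.76 to 76.2 CPM (4.34 ± 0.22) and the efflux carrier gene DTX3 from 0.932 to 41 CPM (5.46 ± 0.28; edgeR adjusted p at most 4.81e-07 for these). Among 30 genes of glutathione S-transferases and xenobiotic detoxification, 15 rose and 1 fell (median 0.593, camera adjusted p = 1.02e-05, or adjusted p = 0.523 with an estimated correlation), with GSTU25 (4.18 ± 0.25), CYP81D11 (1.94 ± 0.19) and GSTU1 (1.51 ± 0.15) rising. Of 16 flavonoid and anthocyanin genes, 14 rose (15 over the list alone) and none fell (median 2.896, or 2.705 with its 1 near-empty member MYB90 at a floor of 3 counts, camera adjusted p = 8.12e-12, or adjusted p = 0.111 with an estimated correlation). DFR (5.45 ± 0.33), GSTF12 (4.54 ± 0.30), which carries anthocyanin to the vacuole, and UGT78D2 (0.99 ± 0.07) were among them. Of 14 phosphate starvation genes, 9 rose and none fell (median 1.152, camera adjusted p = 8e-06, or adjusted p = 0.208 with an estimated correlation), among them PAP17 (1.52 ± 0.16), PHT1;4 (1.41 ± 0.14) and SPX1 (1.2 ± 0.12).

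Of 46 nuclear photosynthesis genes, 38 fell in Col-0 and none rose (median −0.693, camera adjusted p = 1.02e-20, or adjusted p = 0.339 with an estimated correlation). The ferredoxin gene FED A (−2.02 ± 0.14) and the photosystem I subunit genes PSAN (−1.76 ± 0.11) and PSAF (−1.62 ± 0.13) fell most clearly, all within the electron path that methyl viologen diverts (edgeR adjusted p at most 7.33e-06 for these). Antioxidant enzymes were mixed: 6 rose and 10 fell of 25 (median −0.09, camera adjusted p = 0.181). The iron superoxide dismutase gene FSD1 fell (−2.26 ± 0.12), the stromal ascorbate peroxidase gene SAPX fell (−1.24 ± 0.12), and the glutathione and ascorbate recycling genes GR1 (0.89 ± 0.07) and DHAR2 (1.25 ± 0.10) rose. Of 5 ROS hallmark genes, UPOX rose and the others gave −0.01 ± 0.23 for TI1, −0.29 ± 0.32 for AT1G19020, −0.19 ± 0.29 for HCYSTM1 and −1.51 ± 0.79 for AT1G57630 (edgeR adjusted p at least 0.18 for each of these others). AT1G57630 passed without Col-0 control replicate 1 and with 2 libraries left out (−2.02 in both fits), and HCYSTM1 turned to 0.42 with the root marker covariate. The hallmark list had a median of −0.188 but a mean of 0.271, and camera pointed up without passing (camera adjusted p = 0.639). It passed with the root marker covariate (median 0.422) and with fry (fry adjusted p = 0.0342), range 0.0342 to 0.942.

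Salicylic acid genes, which mark defence against biotrophic pathogens, fell in part: 8 of 23 fell and none rose (median −1.302, camera adjusted p = 0.0062, or adjusted p = 0.817 with an estimated correlation), among them WRKY70 (−2.37 ± 0.38), DLO1 (−1.98 ± 0.30) and WRKY54 (−1.95 ± 0.28). The Col-0 control libraries differed in these genes: PR1 stood at 0.391, 121 and 84.8 CPM in them, and the list's mean level at 1.94, 4.18 and 3.44. The salicylic acid call was lost without Col-0 control replicate 2 (median −0.465) and with the root marker covariate (median −0.65), range 2.62e-07 to 0.817. Fry lost it as well (fry adjusted p = 0.184). Expansins, which loosen cell walls, had 4 of 8 falling and 1 rising (5 and 1 over the list alone, median −0.35, camera adjusted p = 0.0282, or adjusted p = 0.229 with an estimated correlation). EXPA8 stood at −1.38 ± 0.18 and EXP3 at −0.63 ± 0.09. That call was lost without Col-0 control replicate 3 (camera adjusted p = 0.0613), without med8 control replicate 3 (0.0587) and with the root marker covariate (0.0571), range 0.000414 to 0.229. Root tissue markers fell in 6 and rose in 2 of 15 (8 and 2 over the list alone, median −0.967, camera adjusted p = 0.0168, or adjusted p = 0.817 with an estimated correlation). The peroxidase genes PRX1 (−2.18 ± 0.45) and PRX2 (−2.15 ± 0.39) fell, and the phosphate exporter gene PHO1 rose (0.54 ± 0.10). The root marker call was lost without Col-0 methyl viologen replicate 3 (median −0.865), range 9.31e-05 to 0.817.

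All 19 circadian clock genes passed the test in Col-0, 10 higher and 9 lower on methyl viologen (camera adjusted p = 0.639). The morning genes LHY (2.79 ± 0.18), CCA1 (2.65 ± 0.17, 15.4 to 96.9 CPM) and RVE8 (2.55 ± 0.16) rose, and the evening genes GI (−0.74 ± 0.08) and TOC1 (−0.73 ± 0.08) fell. The difference between morning and evening genes stood at −3.7, −4.03 and −3.68 in the Col-0 controls and at 0.19, −0.42 and −0.64 in Col-0 on methyl viologen, and this shift accompanied every gene group above. The mean level of the root markers stood at 3, 3.17 and 3.41 in the controls and at 2.04, 2.89 and 1.99 on methyl viologen.

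Other lists did not pass camera in Col-0. In the abscisic acid and dehydration list 9 rose and 5 fell of 21 (camera adjusted p = 0.639): the phosphatase gene HAB1 rose (1.23 ± 0.10), and the cold and dehydration genes KIN2 (−1.94 ± 0.17) and COR15B (−1.80 ± 0.18) fell. Of 27 jasmonate genes 7 rose and 1 fell (7 and 3 over the list alone), with a median of 0.103, a mean of −0.116 and camera pointing up (camera adjusted p = 0.423), and the allene oxide cyclase gene AOC1 rose (1.41 ± 0.21). Of 26 glucosinolate and camalexin genes 6 rose and 2 fell (median 0.253, camera adjusted p = 0.123), with CYP71A13 (2.41 ± 0.23) and CYP79F2 (1.32 ± 0.14) rising. Touch and handling genes had 1 rising and 4 falling of 15 (1 and 6 over the list alone, median −0.273, camera adjusted p = 0.106). CBF1 stood at −2.50 ± 0.38 and DREB1A at −1.35 ± 0.20. Of 30 Mediator subunit genes 2 rose, MED23 and SFR6 (0.38 ± 0.06 and 0.38 ± 0.08), and MED10B fell (−0.48 ± 0.08, camera adjusted p = 0.639 for the list). In the senescence list 2 rose and 2 fell of 11, with SAG29 at 5.09 ± 0.27 and NYC1, a chlorophyll b reductase gene, at −2.69 ± 0.37 (camera adjusted p = 0.878).

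In the remaining lists in Col-0, 2 heat shock genes rose and 1 fell of 18, with HSP70 at 0.99 ± 0.13 (camera adjusted p = 0.395). The ethylene and jasmonate defence genes had 2 falling of 6, HCHIB (−1.03 ± 0.29) and PDF1.2 (−3.25 ± 0.93), and a median of −0.669 (camera adjusted p = 0.475). Of 10 flowering time genes 1 fell, SVP (−0.45 ± 0.08, camera adjusted p = 0.637 for the list), and of 24 cell division genes 1 rose, the ribonucleotide reductase gene TSO2 (1.21 ± 0.12, camera adjusted p = 0.864 for the list, median −0.028, mean 0.002). None of 12 class III peroxidases passed (camera adjusted p = 0.878, median −0.042, mean 0.046). With the root marker covariate the peroxidases (median 0.583) and the cell division genes (median −0.393) passed, ranges 0.014 to 0.98 and 7.45e-06 to 0.95. Single libraries decided a few of these: without Col-0 control replicate 2 the jasmonate and glucosinolate lists passed (medians 0.339 and 0.349, camera adjusted p = 0.0162 for both), and the glucosinolate list also without Col-0 methyl viologen replicate 2 (median 0.317). Without Col-0 control replicate 1 the touch list (median −0.522) and the ethylene and jasmonate defence list (median −1.789) passed, as they did with 2 libraries left out (−0.519 and −1.785). The camera adjusted p ran from 0.0162 to 0.934 for jasmonate, 0.0162 to 0.817 for glucosinolates, 0.00526 to 0.817 for touch and 8.68e-05 to 0.959 for the defence list. HCHIB lost its call in 4 fits without a library, at the weakest without Col-0 methyl viologen replicate 1 (−0.92), edgeR adjusted p range 9.17e-05 to 0.0818. PDF1.2 also lost its call in 4, at the weakest without Col-0 control replicate 2 (−2.04), range 0.000388 to 0.53.

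Methyl viologen changed 5969 genes in Col-0 (3191 higher, 2778 lower; 28.78% of those tested; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p < 0.05), of which 862 rose and 643 fell at least 2-fold. Of the 24 lists tested, 10 passed camera, 5 up and 5 down, and 0 passed with an estimated correlation. With 99 2-fold and 100 4-fold changes simulated in 20741 genes, edgeR recovered 75.8% and 96%, with 6% of calls false.

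In med8, methyl viologen raised genes for detoxification, anthocyanins, touch responses and both salicylic acid and jasmonate signalling, and lowered nuclear photosynthesis genes. NUDT24 rose 246-fold (0.0563 to 15.1 CPM), the transcription factor genes NAC061 103-fold (to 8.71 ± 5.52 CPM) and ZAT7 82-fold (0.148 to 12.6 CPM). CYP96A5 and the RNA-binding protein gene PUM8 had 0 counts in the med8 controls and reached 1.56 and 1.35 CPM, at least 44.6-fold and at least 39.1-fold. RRTF1, a redox-responsive factor, had 2 counts in the med8 controls and 1.81 ± 1.96 CPM on methyl viologen, a ratio of 81.2 (counting interval 22.2 to 675). The largest falls included MRN1 (17.3-fold, from 3.89 ± 3.57 to 0.226 CPM), CYP71A20 (9.2-fold), the auxin-responsive gene IAA29 (7.77-fold, 14.1 to 1.81 CPM) and the cell wall enzyme gene BXL1 (6.21-fold, 327 to 52.7 CPM). MRN1 lost its call with the root marker covariate (−3.75), and without med8 control replicate 2 the fitted log2 value of NUDT24 went from 7.94 to 11.98.

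All 17 mitochondrial dysfunction genes rose in med8 (median 2.308, camera adjusted p = 1.48e-13, or adjusted p = 0.262 with an estimated correlation), with DTX4 (5.40 ± 0.31), DTX3 (5.29 ± 0.24) and UGT74E2 (4.59 ± 0.21) among them (edgeR adjusted p at most 8.71e-07 for these). Of 30 detoxification genes 22 rose and 2 fell (23 and 3 over the list alone, median 1.103, camera adjusted p = 2.62e-06, or adjusted p = 0.515 with an estimated correlation). Among them were GSTU25 (3.38 ± 0.24), OPR1 (1.80 ± 0.17) and GSTU1 (1.54 ± 0.16). Of 16 flavonoid genes 15 rose (median 3.138, or 3.112 with MYB90 at its floor, camera adjusted p = 2.87e-09, or adjusted p = 0.262 with an estimated correlation). Among them were DFR (4.75 ± 0.30) and UF3GT (4.31 ± 0.33). Of 14 phosphate starvation genes 11 rose (12 over the list alone, median 1.553, camera adjusted p = 7.01e-06, or adjusted p = 0.262 with an estimated correlation). Among them were MGDC (2.25 ± 0.20) and PHT1;4 (1.90 ± 0.15). All 46 nuclear photosynthesis genes fell (median −0.666, camera adjusted p = 2.44e-17, or adjusted p = 0.505 with an estimated correlation). The Rubisco small subunit gene RBCS2B stood at −0.94 ± 0.11, the ferredoxin reductase gene FNR2 at −0.81 ± 0.10 and PSBQA at −0.76 ± 0.09 (edgeR adjusted p at most 6.76e-05 for these).

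All 15 touch and handling genes rose in med8 (median 2.039, camera adjusted p = 8.5e-11, or adjusted p = 0.262 with an estimated correlation). The calmodulin-like gene TCH2 rose from 16.3 to 53.1 CPM (1.70 ± 0.09), the ethylene response factor gene ERF104 from 20.3 to 52.6 CPM (1.37 ± 0.10) and the cold-response factor gene CBF1 from 2.3 to 17.5 CPM (2.93 ± 0.23; edgeR adjusted p at most 4.01e-06 for these). Of 23 salicylic acid genes 13 rose and none fell (17 over the list alone, median 1.347, camera adjusted p = 0.000296, or adjusted p = 0.631 with an estimated correlation). Among them were GRX480 (2.54 ± 0.41), WRKY54 (2.28 ± 0.26) and the isochorismate synthase gene EDS16 (1.77 ± 0.29). Of 27 jasmonate genes 15 rose and none fell (median 0.766, camera adjusted p = 0.000547, or adjusted p = 0.631 with an estimated correlation). Among them were AOC3 (1.93 ± 0.24), the repressor gene JAZ1 (1.88 ± 0.27) and the transcription factor gene MYC2 (1.66 ± 0.11). Of 26 glucosinolate and camalexin genes 13 rose and 2 fell (14 and 2 over the list alone, median 0.476, camera adjusted p = 0.0031, or adjusted p = 0.527 with an estimated correlation). IMS2 stood at 1.70 ± 0.15 and CYP79F2 at 1.43 ± 0.14.

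Of 21 iron deficiency genes 12 rose and 1 fell in med8 (median 0.756, camera adjusted p = 0.000668, or adjusted p = 0.505 with an estimated correlation). The nicotianamine synthase genes NAS2 (3.14 ± 0.34, 11.2 to 98.7 CPM) and NAS1 (1.52 ± 0.12) and the root regulator gene MYB10 (1.80 ± 0.21) rose, whereas BHLH101 fell (−0.78 ± 0.15, 18.6 to 10.9 CPM; edgeR adjusted p at most 0.00142 for these). Of 4 ferritins 2 rose and 1 fell (camera adjusted p = 0.869). FER4 stood at −0.81 ± 0.14. Of 21 abscisic acid and dehydration genes 8 rose and 2 fell (9 and 2 over the list alone, median 0.363, camera adjusted p = 0.0355, or adjusted p = 0.665 with an estimated correlation), with NCED3, the entry enzyme of abscisic acid synthesis, at 1.27 ± 0.20 and HAI2 at 2.01 ± 0.34. That call was lost without med8 control replicate 1 (median 0.222), med8 control replicate 3 (median 0.215) or med8 methyl viologen replicate 3 (median 0.257) and with 2 libraries left out (0.215), range 0.000912 to 0.665. Root tissue markers had 9 falling and 1 rising of 15 (11 and 1 over the list alone, median −1.338, camera adjusted p = 0.0457, or adjusted p = 0.733 with an estimated correlation). PRP3 stood at −1.94 ± 0.42 and PHO1 at 1.29 ± 0.10. The root marker call was lost in 8 of the 12 fits without a library and with RLE size factors (camera adjusted p = 0.0663), range 2.72e-05 to 0.842.

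The other lists did not pass camera in med8. UPOX rose (2.53 ± 0.15), as did AT1G19020 (1.01 ± 0.32) and AT1G57630 (2.38 ± 0.77), so that 3 of 5 ROS hallmark genes passed (median 1.014, camera adjusted p = 0.128). The list passed with the root marker covariate (median 1.862) and with fry, range 0.00137 to 0.527. TI1 (0.23 ± 0.24) and HCYSTM1 (−0.48 ± 0.30) did not pass, except TI1 with the root marker covariate (0.8) and HCYSTM1 without med8 control replicate 3 or with 2 libraries left out (−0.78 in both fits). AT1G19020 lost its call without med8 methyl viologen replicate 2 (0.86) or 3 (1.03), edgeR adjusted p range 0.000855 to 0.0882, and stood at 0.66 without med8 control replicate 3. AT1G57630 lost its call in 4 fits without a library, at the weakest without med8 control replicate 3 (1.98), range 0.00431 to 0.116. Antioxidant enzymes had 8 rising and 9 falling of 25 (10 and 9 over the list alone), a median of 0.022, and camera pointing down (camera adjusted p = 0.855). DHAR2 stood at 1.39 ± 0.10 and the peroxiredoxin gene 2CPA at −0.72 ± 0.09. Of 18 heat shock genes 6 rose and 1 fell (median 0.599, camera adjusted p = 0.0784). HSP70 stood at 0.87 ± 0.13 and HSFA7A at −1.26 ± 0.20. Of 19 clock genes 4 rose and 7 fell (median −0.074, mean 0.017, camera adjusted p = 0.499). LHY stood at 1.89 ± 0.18 and PRR7 at −0.84 ± 0.07. The morning minus evening value stood at −3, −3.03 and −2.63 in the med8 controls and at −1.35, −1.58 and −1.85 on methyl viologen, beside the gene groups above. The root marker level stood at 3.28, 3.4 and 1.72 in the med8 controls and at 1.82, 1.87 and 1.8 on methyl viologen.

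Smaller sets in med8 were Mediator subunits (3 rising and 1 falling of 30, or 1 and 1 over the list alone, median −0.006, mean 0.007, camera adjusted p = 0.996; SFR6 at 0.39 ± 0.08) and senescence genes (3 rising and 2 falling of 11, camera adjusted p = 0.98; SEN1 at −1.85 ± 0.28). Expansins had 1 rising and 2 falling of 8 (camera adjusted p = 0.46; EXPA4 at 1.14 ± 0.15 and EXPA8 at −0.99 ± 0.18), and flowering time genes 2 falling of 10 (1 over the list alone, camera adjusted p = 0.398; AGL20, also known as SOC1, at −1.2 ± 0.13). The ethylene and jasmonate defence list had 1 rising of 6, ERF1 (2.24 ± 0.59, camera adjusted p = 0.855 for the list), and the class III peroxidases 1 rising of 12, PRX38 (1.80 ± 0.46, not called with the root marker covariate at 1.86, camera adjusted p = 0.616 for the list). None of 24 cell division genes passed (median 0.142, camera adjusted p = 0.28). The cell division list passed without med8 control replicate 3 (median 0.4) and with 2 libraries left out (median 0.401), and passed downward with the root marker covariate (median −0.213), range 0.000638 to 0.939. With that covariate the peroxidases passed upward (median 1.045, camera adjusted p = 0.00473; range 0.00473 to 0.939).

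Methyl viologen changed 8931 genes in med8 (4528 higher, 4403 lower; 43.06% of those tested), of which 1547 rose and 616 fell at least 2-fold. Of 24 lists, 12 passed camera, 10 up and 2 down, and 0 with an estimated correlation.

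On control medium, med8 differed from Col-0 in fewer genes, with iron shortage genes higher and FT and SEP3 lower. BHLH100 was 6.37-fold higher in med8 (6.05 to 38.6 CPM), the starch regulator gene QQS 4.97-fold (2.81 to 14 CPM), BHLH101 4.77-fold, bHLH38 4.24-fold and ASG4 3.93-fold. The floral inducer gene FT was 13-fold lower (1.4 to 0.103 CPM; −3.70 ± 0.50, edgeR adjusted p = 0.00322), the floral organ gene SEP3 9.26-fold (6.35 to 0.684 CPM), PDF1.4 5.91-fold, the aquaporin gene TIP2;3 5.34-fold (40.9 to 7.66 CPM) and the annexin gene ANNAT7 5.23-fold. PDF1.2, a defensin gene, had −6.65 ± 1.33 (edgeR adjusted p = 0.0168). It stood at 0.358, 18.1 and 6.91 CPM in the Col-0 controls, uneven like PR1, and averaged 0.0805 in med8. When the 2 groups were fitted alone, bHLH38 (2.09), ASG4 (1.98), PDF1.4 (−2.56) and ANNAT7 (−2.39) lost their calls, bHLH38 also with 2 libraries left out (1.82). PDF1.2 lost its call without med8 control replicate 2 (−6.28) or replicate 3 (−6.30), range 2.85e-06 to 0.117.

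Of 21 iron deficiency genes 10 were higher in med8 on control medium and none lower (11 higher and 2 lower over the list alone, median 0.45, camera adjusted p = 2.42e-05, or adjusted p = 0.69 with an estimated correlation). IMA2 (2.32 ± 0.25, 4.24 to 21.3 CPM), BHLH101 (2.25 ± 0.16) and bHLH38 (2.08 ± 0.32) were higher, and IRT1 had 0.09 ± 0.37 (edgeR adjusted p = 0.921). No ferritin passed (1 lower over the list alone, camera adjusted p = 0.227). FER1 stood at −0.94 ± 0.30 and passed without Col-0 control replicate 1 (−1.19) and with DESeq2 (−0.93). FER3 stood at −0.25 ± 0.13 and passed without med8 control replicate 3 or with 2 libraries left out (−0.42 in both fits) and with the root marker covariate (−0.38). Of 17 mitochondrial dysfunction genes 6 were higher and none lower (8 over the list alone, median 0.32, camera adjusted p = 0.0143, or adjusted p = 0.69 with an estimated correlation). Among them were DTX3 (2.24 ± 0.31) and UGT74E2 (0.96 ± 0.22). That call was lost without Col-0 control replicate 1 (median 0.256) or med8 control replicate 1 (median 0.195), range 7.97e-05 to 0.69. The median was 0.488 without Col-0 control replicate 2.

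Of 27 jasmonate genes 3 were lower in med8 and none higher (6 over the list alone, median −0.361, camera adjusted p = 0.000501, or adjusted p = 0.69 with an estimated correlation): the storage protein genes VSP1 (−1.45 ± 0.24) and VSP2 (−1.04 ± 0.19), and LOX2 (−1.47 ± 0.31). The call was lost without Col-0 control replicate 2 (median −0.14), range 7.45e-09 to 0.69, and the median was −0.598 without Col-0 control replicate 1. VSP1 and VSP2 lost their calls with 2 libraries left out (−1.39 and −1.04). LOX2 lost its call in 5 fits without a library, at the weakest without Col-0 control replicate 2 (−0.99), edgeR adjusted p range 3.24e-05 to 0.133. Of 6 ethylene and jasmonate defence genes 3 were lower (4 over the list alone, median −1.253, camera adjusted p = 0.0175, or adjusted p = 0.69 with an estimated correlation), PDF1.2, PDF1.3 (−4.36 ± 1.02) and PR4 (−1.29 ± 0.31). The call was lost without med8 control replicate 3 (median −2.449), range 1.08e-08 to 0.69. The median was −3.252 without Col-0 control replicate 1, −3.849 and −2.906 without med8 control replicates 1 and 2, and −2.822 without any 1 library on methyl viologen. PDF1.3 and PR4 lost their calls in 5 and 9 fits without a library, at the weakest without med8 control replicate 3 for PDF1.3 (−3.83) and Col-0 control replicate 2 for PR4 (−1), edgeR adjusted p ranges 0.00307 to 0.183 and 0.000703 to 0.172. PDF1.3 stood at −7.34 without med8 control replicate 1. Of 14 phosphate starvation genes 2 were lower (5 over the list alone, median −0.288, camera adjusted p = 0.0378, or adjusted p = 0.69 with an estimated correlation). That call was lost without Col-0 control replicate 2 (median −0.129), med8 control replicate 2 (median −0.307) or med8 control replicate 3 (median −0.258), range 0.00379 to 0.69. Its median was −0.434 without Col-0 control replicate 1.

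Of 30 detoxification genes 1 was higher and 2 lower in med8 on control medium (2 and 2 over the list alone, median −0.238, camera adjusted p = 0.0468, or adjusted p = 0.868 with an estimated correlation). GSTU25 stood at 1.2 ± 0.23 and GSTU2 at −1.01 ± 0.23. It was lost without Col-0 control replicate 2 (median −0.129) or replicate 3 (median −0.173), Col-0 methyl viologen replicate 2 (median −0.238) or med8 control replicate 3 (median −0.062), range 0.00165 to 0.868. Its median was −0.367 without Col-0 control replicate 1 and −0.371 without med8 control replicate 1. GSTU25 lost its call in 3 fits without a library, at the weakest without Col-0 control replicate 3 (1.18), and GSTU2 in 2, at the weakest without Col-0 control replicate 2 (−0.97), edgeR adjusted p ranges 1.34e-05 to 0.113 and 0.000641 to 0.163. None of 46 nuclear photosynthesis genes passed alone, and the list passed upward (median 0.083, camera adjusted p = 0.0456, or adjusted p = 0.868 with an estimated correlation). That call was lost in 6 fits without a library, including those without Col-0 control replicate 2 (median 0.035) and med8 control replicate 3 (median 0.04), range 1.59e-06 to 0.868. Its median was 0.049 without Col-0 control replicate 3, 0.169 without Col-0 control replicate 1 and 0.138 without med8 control replicate 1. Root tissue markers had 1 of 15 lower, PHO1 (−0.46 ± 0.10), and passed downward (median −0.347, camera adjusted p = 0.0339, or adjusted p = 0.868 with an estimated correlation). That call was lost without Col-0 control replicate 3 (median −0.184) and the median turned to 0.049 without med8 control replicate 3 (camera adjusted p = 0.535; range 0.000557 to 0.993). The root marker level of that library was 1.72, against 3.28 and 3.4 in the other med8 controls. The median was −0.527 without med8 control replicate 1. PHO1 lost its call without Col-0 control replicate 2 or 3 (−0.48 in both fits), edgeR adjusted p range 0.0022 to 0.124.

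Of 10 flowering time genes 1 was higher in med8 and 3 lower (2 and 6 over the list alone, median −0.475, camera adjusted p = 0.0946). Besides FT, the MADS-box gene AGL8, also known as FUL, was lower (−1.38 ± 0.33), and the floral repressor gene FLC was higher (1.68 ± 0.36, 0.773 to 2.48 CPM, edgeR adjusted p = 0.0207). FLC lost its call without Col-0 control replicate 3 (1.67) or med8 control replicate 2 (1.66), range 0.0002 to 0.126. Of 19 clock genes 5 were higher and 4 lower (11 and 6 over the list alone, camera adjusted p = 0.199). ELF4 stood at −0.91 ± 0.08 and TOC1 at −0.46 ± 0.08. Of 15 touch genes 3 were higher (4 over the list alone, median −0.051, mean 0.132, camera adjusted p = 0.145). Among them was CBF2 (1.51 ± 0.18). Of 5 ROS hallmark genes TI1 was lower (−1.34 ± 0.24, 35.1 to 13.8 CPM, edgeR adjusted p = 0.0103) but not when the 2 groups were fitted alone (range 4.42e-06 to 0.0866), UPOX had 0.46 ± 0.17 (edgeR adjusted p = 0.131), and AT1G19020, HCYSTM1 and AT1G57630 had −0.30 ± 0.33, −0.54 ± 0.29 and −1.2 ± 0.79 (1 higher and 1 lower over the list alone, camera adjusted p = 0.199 for the list).

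Of 23 salicylic acid genes 1 was lower (0 over the list alone, median −0.51, camera adjusted p = 0.393), PR1 (−5.92 ± 1.52, edgeR adjusted p = 0.0447). Its call was lost in 11 of the 12 fits without a library, range 0.00418 to 0.185 and the libraries of both groups overlapped. Mediator subunits had 1 higher and 1 lower besides MED8 itself, SWP (0.20 ± 0.05) and MED10B (−0.46 ± 0.08, not called at −0.45 when the 2 groups were fitted alone, camera adjusted p = 0.617 for the list). Antioxidant enzymes had 2 higher of 25 (4 higher and 3 lower over the list alone), a median of −0.032 and camera pointing up (camera adjusted p = 0.886). CAT2 stood at 0.56 ± 0.12. Flavonoid genes had 2 lower of 16 (2 higher and 2 lower over the list alone, median −0.01, mean 0.021, or a median of 0.067 with MYB90 at its floor, camera adjusted p = 0.865), MYB12 (−0.92 ± 0.17) and FLS1 (−0.58 ± 0.12). The abscisic acid list had 1 higher of 21, HAB1 (0.42 ± 0.10; 2 higher and 3 lower over the list alone, camera adjusted p = 0.805). The glucosinolate list had 1 higher of 26, CYP71A13 (0.97 ± 0.23, median −0.034, mean 0.018, camera adjusted p = 0.886). Single-gene calls here were lost without single libraries. The weakest fits were those without Col-0 control replicate 3 for SWP (0.20), CAT2 (0.48), FLS1 (−0.48), HAB1 (0.40) and CYP71A13 (0.87), and without Col-0 control replicate 2 for MYB12 (−0.87). The edgeR adjusted p ran from 0.00426 to 0.144 for SWP, 0.000514 to 0.1 for CAT2, 0.000534 to 0.136 for FLS1, 0.00344 to 0.128 for HAB1, 0.000716 to 0.159 for CYP71A13 and 0.000153 to 0.113 for MYB12.

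Class III peroxidases had 1 higher of 12, PRX5 (1.82 ± 0.42, list median −0.399, camera adjusted p = 0.227), and senescence genes 1 higher of 11, SAG29 (1.3 ± 0.31, list median −0.335, camera adjusted p = 0.227). No heat shock gene passed (median −0.079, camera adjusted p = 0.344; HSP70 at −0.04 ± 0.13), nor any of 8 expansins (1 higher and 1 lower over the list alone, median 0.008, camera pointing down with camera adjusted p = 0.886; EXPA11 at 0.39 ± 0.10) or 24 cell division genes (median 0.129, camera adjusted p = 0.132). Without Col-0 control replicate 1 the lists that passed camera included salicylic acid (median −0.766), cell division (median 0.283), heat shock (median −0.167), peroxidases (median −0.654) and senescence (median −0.368), and without Col-0 control replicate 2 they included touch (median 0.39) and flowering time (median −0.461). Flowering time also passed without Col-0 control replicate 3 (median −0.484), and cell division without med8 control replicate 1 (median 0.234) or 2 (median 0.243). With 2 libraries left out, salicylic acid, heat shock and glucosinolate genes passed downward. The adjusted p ran from 0.00023 to 0.935 for salicylic acid, 0.0235 to 0.868 for touch, 0.0365 to 0.69 for flowering time, 0.00393 to 0.868 for cell division, 0.0174 to 0.868 for heat shock, 0.0166 to 0.868 for peroxidases, 0.039 to 0.868 for senescence and 0.0198 to 0.956 for glucosinolates. PRX5 and SAG29 each lost their calls in 4 fits without a library, at the weakest without Col-0 control replicate 2 (1.72 and 1.06), edgeR adjusted p ranges 0.00106 to 0.159 and 0.00178 to 0.127.

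On control medium 1200 genes differed between med8 and Col-0 (582 higher, 618 lower; 5.79% of those tested), of which 95 were higher and 182 lower at least 2-fold. The count went to 446 without Col-0 control replicate 2, 402 without Col-0 control replicate 3 and 631 without med8 control replicate 2. It went to 1976 with DESeq2, 2497 with the root marker covariate, 1848 with 2 libraries left out and 143 when the 2 groups were fitted alone. Of 24 lists 8 passed camera, 3 up and 5 down, and 0 with an estimated correlation; 3 passed without med8 control replicate 3. With the root marker covariate the detoxification (−0.151), defence (−1.136), photosynthesis (0.054), phosphate (−0.259) and root marker (−0.091) lists lost their calls.

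On methyl viologen, med8 stood above Col-0 in touch, salicylic acid, mitochondrial stress and ferritin genes, and below it in 12 of 21 iron deficiency genes and in FT, SEP3 and AGL20. CBF1 was 96.3-fold higher in med8 (0.18 to 17.5 CPM; edgeR adjusted p = 3.68e-07), the cell death suppressor gene BAP2 142-fold (0.0465 to 7.21 CPM) and NAC061 110-fold (0.0754 to 8.71 CPM). CYP96A5 was at least 54.8-fold higher, with 0 counts in Col-0, and RRTF1 had 1 count in Col-0 and a ratio of 199 (counting interval 35.4 to 7910). LEA7 was 47.7-fold lower in med8 (14.5 to 0.3 CPM), FT 22.8-fold (2.59 to 0.113 CPM; −4.51 ± 0.45, edgeR adjusted p = 4.39e-05), SEP3 15.6-fold (3.2 to 0.204 CPM), the GATA factor gene CGA1 9.41-fold (10.7 to 1.14 CPM), SAG29 9-fold and PDF1.4 8.9-fold.

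All 15 touch and handling genes were higher in med8 on methyl viologen (median 2.252, camera adjusted p = 7.24e-18, or adjusted p = 0.081 with an estimated correlation). CBF2 stood at 4.19 ± 0.19, ERF104 at 1.97 ± 0.10 and TCH2 at 1.63 ± 0.09. Of 23 salicylic acid genes 14 were higher and none lower (16 over the list alone, median 1.894, camera adjusted p = 4.25e-08, or adjusted p = 0.539 with an estimated correlation). WRKY70 stood at 4.27 ± 0.40 (6.22 to 120 CPM), WRKY54 at 3.73 ± 0.28 and FMO1, a gene of systemic acquired resistance, at 5.69 ± 0.66. PR1 had 1.67 ± 1.38 (edgeR adjusted p = 0.426). Of 21 iron deficiency genes 5 were higher and 12 lower (median −1.375, camera adjusted p = 4.77e-05, or adjusted p = 0.459 with an estimated correlation). IMA3 (−2.06 ± 0.12), BTS (−1.72 ± 0.11) and BHLH101 (−2.11 ± 0.15) were lower, and NAS2 (2.12 ± 0.32) and the root ferric reductase gene FRO2 (1.24 ± 0.34) were higher. All 4 ferritins were higher (median 1.886, camera adjusted p = 0.000247, or adjusted p = 0.081 with an estimated correlation). FER1 stood at 2.72 ± 0.33 and FER4 at 2.50 ± 0.16. Of 17 mitochondrial dysfunction genes 9 were higher and none lower (11 and 1 over the list alone, median 0.587, camera adjusted p = 9.67e-05, or adjusted p = 0.459 with an estimated correlation). DTX4 stood at 3.13 ± 0.26, DTX3 at 2.08 ± 0.20 and the alternative oxidase gene AOX1A at 0.69 ± 0.11. Beside these groups the morning minus evening clock value lay between −0.64 and 0.19 in Col-0 and between −1.85 and −1.35 in med8, and the root marker level between 1.99 and 2.89 in Col-0 and between 1.8 and 1.87 in med8.

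Of 24 cell division genes 4 were higher and 1 lower (3 and 1 over the list alone, median 0.301, camera adjusted p = 0.00811, or adjusted p = 0.952 with an estimated correlation). CYCB2;3 stood at 0.78 ± 0.19 and TSO2 at −0.79 ± 0.12. The cell division call was lost without Col-0 methyl viologen replicate 2 (median 0.158) and with the root marker covariate (median 0.094), range 0.000721 to 0.952. Among lists that did not pass, the photosynthesis list had 10 higher and 4 lower of 46 (median 0.107, camera adjusted p = 0.113). It passed without Col-0 methyl viologen replicate 2 (median 0.156) or med8 methyl viologen replicate 2 or 3 (median 0.143 in both fits), range 0.0109 to 0.952. FED A stood at 1.35 ± 0.13 and RBCS1B at −0.78 ± 0.13. Antioxidant enzymes had 5 higher and 4 lower of 25 (6 and 4 over the list alone, median 0.114, camera adjusted p = 0.164). FSD1 stood at 1.59 ± 0.12 and the catalase gene CAT3 at 1.53 ± 0.21. Of 27 jasmonate genes 7 were higher and 5 lower (10 and 7 over the list alone, camera adjusted p = 0.382). LOX4 stood at 2.23 ± 0.40, MYC2 at 1.05 ± 0.11 and VSP1 at −1.50 ± 0.24. The abscisic acid list had 9 higher and 4 lower of 21 (9 and 5 over the list alone, median −0.004, mean 0.209, camera adjusted p = 0.334). NCED3 stood at 2.50 ± 0.21 and RAB18 at −2.39 ± 0.36. The glucosinolate list had 6 higher and 2 lower of 26 (8 and 3 over the list alone, median 0.343, camera adjusted p = 0.0601). CYP79F1 stood at 1.25 ± 0.29 and CYP71A13 at −1.26 ± 0.22. It passed with RLE size factors (camera adjusted p = 0.0481), with 2 libraries left out (0.0314) and without Col-0 methyl viologen replicate 1 (median 0.419) or 3 (0.385), med8 control replicate 3 (0.345) or med8 methyl viologen replicate 2 (0.365), range 0.0188 to 0.81.

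Of 10 flowering time genes 2 were higher and 4 lower in med8 on methyl viologen (median −0.491, camera adjusted p = 0.147). FLC stood at 1.44 ± 0.33, SVP at 0.43 ± 0.08 and AGL20 at −1.33 ± 0.13. Of 19 clock genes 5 were higher and 9 lower (median −0.316, camera adjusted p = 0.147). RVE1 stood at −2.47 ± 0.21 and FKF1 at 1.03 ± 0.11. Of 5 ROS hallmark genes AT1G19020 (1.01 ± 0.32) and AT1G57630 (2.70 ± 0.78) were higher and TI1 (−1.1 ± 0.24) lower, while UPOX had −0.37 ± 0.14 and HCYSTM1 −0.83 ± 0.29 (2 higher and 3 lower over the list alone, median −0.367, mean 0.282, camera adjusted p = 0.69). UPOX passed without Col-0 methyl viologen replicate 2 (−0.48), and both UPOX and HCYSTM1 passed without med8 control replicate 3 (−0.37 and −0.83), with 2 libraries left out, with only the 2 groups fitted, with DESeq2 and with the root marker covariate. AT1G19020 lost its call in 8 fits without a library and AT1G57630 in 5, both at the weakest without Col-0 methyl viologen replicate 1 (0.83 and 2.46), edgeR adjusted p ranges 0.00148 to 0.146 and 0.000862 to 0.101. Detoxification genes had 3 higher and 2 lower of 30 (1 and 2 over the list alone, camera adjusted p = 0.721; GSTU9 at 0.77 ± 0.24 and CYP81D11 at −1.14 ± 0.19). Phosphate starvation genes had 2 higher and 3 lower of 14 (2 and 4 over the list alone, camera adjusted p = 0.912; MGD2 at 0.73 ± 0.10 and PAP17 at −0.64 ± 0.15), and heat shock genes 2 higher and 3 lower of 18 (camera adjusted p = 0.69; HSFB2A at 1.35 ± 0.21 and HSFA7A at −1.16 ± 0.20).

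Of 11 senescence genes 1 was higher and 3 lower (median 0.014, mean −0.229, camera adjusted p = 0.428; SAG29 at −3.17 ± 0.23), and of 8 expansins 3 were higher (4 over the list alone, median 0.226, camera adjusted p = 0.109; EXPA11 at 0.79 ± 0.10). The expansins passed without Col-0 methyl viologen replicate 2 (median 0.249), range 0.00631 to 0.459. The ethylene and jasmonate defence list had 1 lower of 6, PR4 (−0.98 ± 0.31; 1 higher and 3 lower over the list alone, camera adjusted p = 0.533 for the list). Flavonoid genes had 2 lower of 16, FLS1 (−0.46 ± 0.11) and TT5 (−0.31 ± 0.10; 1 over the list alone, list median −0.021, mean 0.011, camera adjusted p = 0.912). Root tissue markers had 2 lower of 15, PRP1 (−2.64 ± 0.44) and PRP3 (−1.64 ± 0.42, camera adjusted p = 0.382 for the list), and Mediator subunits had 1 lower besides MED8, RFR1 (−0.29 ± 0.09; 0 over the list alone, median −0.01, mean 0.005, camera adjusted p = 0.912). No class III peroxidase passed (median 0.017, mean −0.148, camera adjusted p = 0.912). Calls were lost without single libraries for PR4, FLS1, TT5, PRP3 and RFR1. Their weakest fits were those without med8 methyl viologen replicate 3 for PR4 (−0.92), med8 methyl viologen replicate 2 for FLS1 (−0.43) and TT5 (−0.25), Col-0 methyl viologen replicate 2 for PRP3 (−1.14) and Col-0 methyl viologen replicate 1 for RFR1 (−0.27). The edgeR adjusted p ran from 0.000302 to 0.12 for PR4, 0.00053 to 0.0545 for FLS1, 0.0111 to 0.141 for TT5, 0.0003 to 0.0661 for PRP3 and 0.000549 to 0.118 for RFR1. In all, 4906 genes differed on methyl viologen (2231 higher, 2675 lower; 23.65% of those tested), of which 802 were higher and 509 lower at least 2-fold, and the count went to 3211 without med8 methyl viologen replicate 2. Of 24 lists 6 passed camera, 5 up and 1 down, and 0 with an estimated correlation.

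The responses of both genotypes to methyl viologen differed in iron, ferritin, touch, salicylic acid and clock genes, as tested by the interaction (response in med8 minus response in Col-0). BHLH100 went from 6.05 to 245 CPM in Col-0 and from 38.6 to 37.8 CPM in med8 (interaction −5.37 ± 0.39, edgeR adjusted p = 2.01e-05). The ubiquitin ligase gene BTS went from 159 to 768 CPM in Col-0 and from 243 to 232 CPM in med8 (−2.34 ± 0.15, edgeR adjusted p = 8.28e-06). FER4 went from 35.6 to 3.49 CPM in Col-0 and from 34.5 to 19.8 CPM in med8 (2.55 ± 0.22, edgeR adjusted p = 3.55e-05). WRKY70 went from 32 ± 16.6 to 6.22 CPM in Col-0 and from 29 to 120 CPM in med8 (4.41 ± 0.52, edgeR adjusted p = 0.000301).

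**Figure D1:**
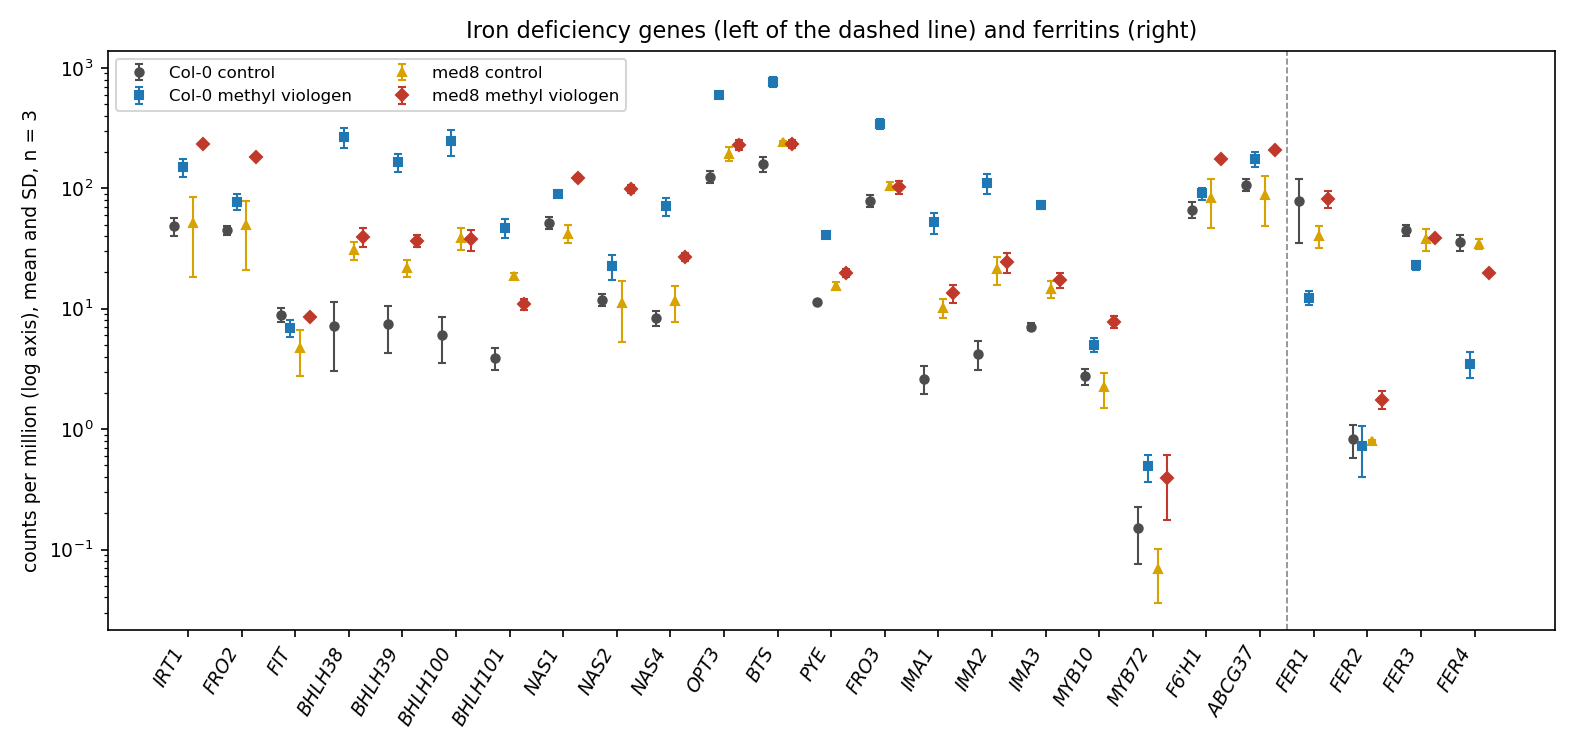
CPM (log axis) of the 21 iron deficiency genes and, right of the dashed line, the 4 ferritins, with 1 symbol for the mean of each group and bars for the SD of its 3 libraries. BHLH100 averages 6.05, 245, 38.6 and 37.8 CPM, and FER4 35.6, 3.49, 34.5 and 19.8 CPM, in Col-0 control, Col-0 methyl viologen, med8 control and med8 methyl viologen.

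Of 21 iron deficiency genes 3 had a positive and 12 a negative interaction (4 and 12 over the list alone, median −1.879, camera adjusted p = 1.85e-06, or adjusted p = 0.324 with an estimated correlation). The 12 negative ones were the regulator genes bHLH38, bHLH39, BHLH100, BHLH101, PYE and BTS, the peptide genes IMA1, IMA2 and IMA3, and OPT3, FRO3 and NAS4. FRU, also known as FIT (1.23 ± 0.35), NAS1 (0.73 ± 0.16) and NAS2 (2.19 ± 0.46) were positive, and IRT1 (0.56 ± 0.52) did not pass. Of 4 ferritins 3 were positive (4 over the list alone, median 1.935, camera adjusted p = 6.15e-05, or adjusted p = 0.0635 with an estimated correlation). FER1 stood at 3.66 ± 0.44 and FER3 at 1.00 ± 0.18. All 15 touch genes were positive (median 2.314, camera adjusted p = 4.28e-17, or adjusted p = 0.0909 with an estimated correlation). CBF1 stood at 5.43 ± 0.43, WRKY40 at 4.06 ± 0.57 and ZAT10 at 2.99 ± 0.35. Of 23 salicylic acid genes 16 were positive and none negative (19 over the list alone, median 2.92, camera adjusted p = 1.01e-08, or adjusted p = 0.686 with an estimated correlation). WRKY54 stood at 4.24 ± 0.38 and DLO1 at 2.92 ± 0.41. Of 27 jasmonate genes 8 were positive and none negative (median 0.619, camera adjusted p = 0.00274, or adjusted p = 0.854 with an estimated correlation). LOX4 stood at 2.59 ± 0.58, JAZ1 at 2.02 ± 0.37 and MYC2 at 1.26 ± 0.15. The jasmonate median was 0.253 without Col-0 control replicate 2.

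All 19 clock genes passed the interaction test, 8 positive and 11 negative (median −0.9, camera adjusted p = 0.218). RVE1 stood at −3.14 ± 0.29, CCA1 at −1.94 ± 0.24 and FKF1 at 1.35 ± 0.16. Of 5 ROS hallmark genes AT1G57630 was positive (3.89 ± 1.1, edgeR adjusted p = 0.038) and UPOX negative (−0.83 ± 0.21, edgeR adjusted p = 0.0246), and AT1G19020 (1.31 ± 0.46), HCYSTM1 (−0.29 ± 0.41) and TI1 (0.24 ± 0.33) did not pass (2 positive and 1 negative over the list alone, camera adjusted p = 0.685). AT1G19020 passed without med8 control replicate 1 (1.63), with 2 libraries left out (1.08), with DESeq2 (1.29) and with the root marker covariate (1.49). AT1G57630 lost its call in 9 fits without a library, at the weakest without Col-0 control replicate 2 (2.38), and UPOX in 4, at the weakest without Col-0 control replicate 3 (−0.75), edgeR adjusted p ranges 0.00676 to 0.11 and 0.00125 to 0.0681.

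**Figure D2:**
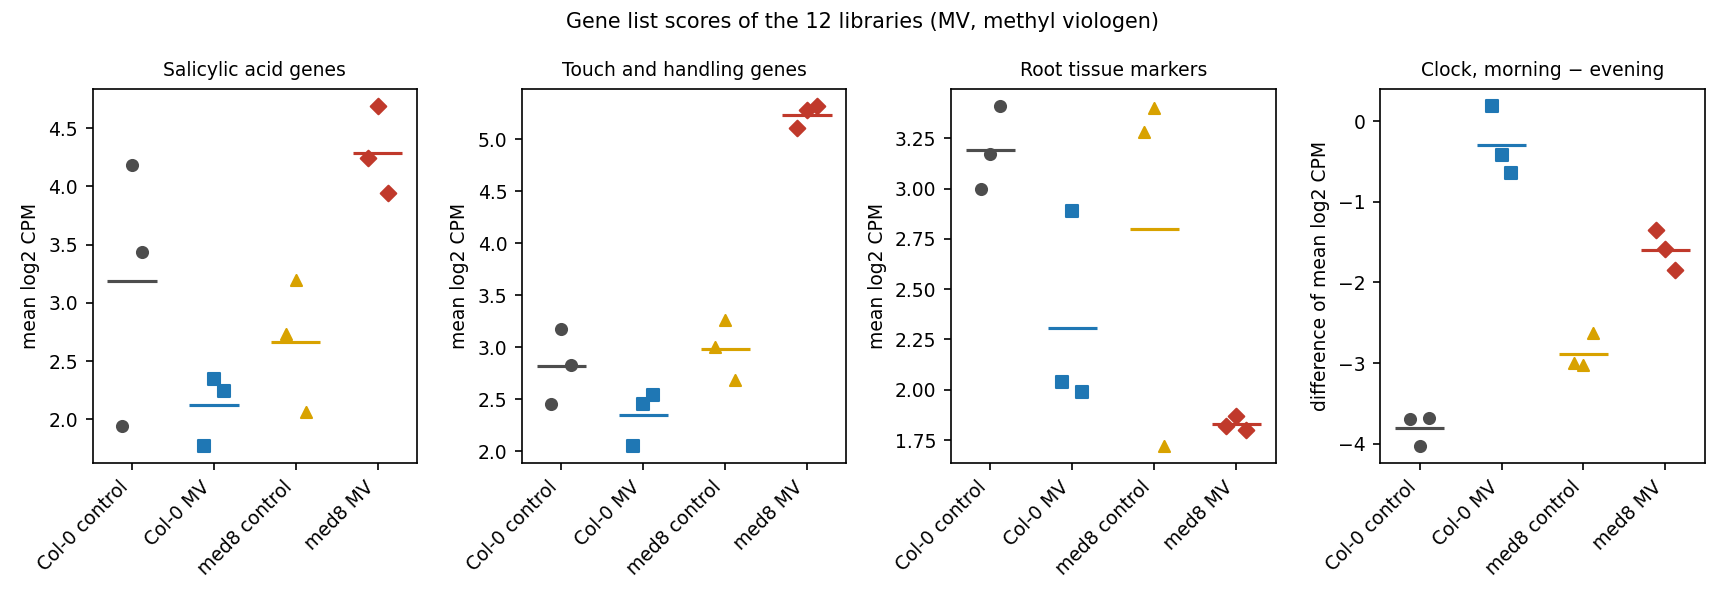
Mean log2 CPM of salicylic acid genes, touch genes and root markers, and the difference in mean log2 CPM between morning and evening clock genes, with 1 symbol for each of the 12 libraries by group and a line at the group mean. The touch level is 5.11, 5.28 and 5.32 in med8 on methyl viologen and lies between 2.05 and 3.26 in the other libraries.

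Other lists did not pass camera for the interaction. Of 25 antioxidant genes 5 were positive and 2 negative (7 and 2 over the list alone, camera adjusted p = 0.301). CAT3 stood at 2.26 ± 0.30, FSD1 at 1.62 ± 0.17 and SAPX at 1.59 ± 0.17. Of 21 abscisic acid genes 7 were positive and 3 negative (7 and 5 over the list alone, median 0.028, camera adjusted p = 0.322). COR15B stood at 2.62 ± 0.25, KIN2 at 2.17 ± 0.24 and HAB1 at −0.97 ± 0.14. Of 46 photosynthesis genes 4 were positive and 2 negative (camera adjusted p = 0.832). FED A stood at 1.18 ± 0.19 and RBCS1B at −0.77 ± 0.18. Of 17 mitochondrial dysfunction genes 2 were positive and 2 negative (camera adjusted p = 0.379). BCS1 stood at 3.16 ± 0.57 and AT12CYS2 at −2.09 ± 0.39. Detoxification genes had 2 positive and 1 negative of 30 (1 and 1 over the list alone, median 0.316, camera adjusted p = 0.176; GSTU10 at 0.95 ± 0.22), heat shock genes 2 positive of 18 (camera adjusted p = 0.405; HSFB2A at 1.37 ± 0.30), and phosphate starvation genes 2 positive of 14 (3 over the list alone, camera adjusted p = 0.26; MGDC at 1.84 ± 0.28). The glucosinolate list had 1 positive and 1 negative of 26 (median 0.339, camera adjusted p = 0.0874), TGG2 (1.02 ± 0.20) and CYP71A13 (−2.23 ± 0.31).

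Senescence genes had 1 positive and 1 negative interaction of 11 (1 and 3 over the list alone, median 0.375, mean 0.075, camera pointing down with camera adjusted p = 0.979), NYC1 (1.94 ± 0.50) and SAG29 (−4.47 ± 0.38). Root tissue markers had 1 positive and 1 negative of 15, PHO1 (0.75 ± 0.14) and PRP1 (−2.38 ± 0.65), with a median of −0.287 and camera pointing up (camera adjusted p = 0.875). NYC1 lost its call in 5 fits without a library, at the weakest without med8 control replicate 3 (1.91), and PRP1 in 8, at the weakest without med8 methyl viologen replicate 2 (−2.15), edgeR adjusted p ranges 0.000303 to 0.0992 and 0.00107 to 0.0835. One gene each passed among expansins (EXP3, 0.52 ± 0.13; 3 over the list alone, median 0.309, camera adjusted p = 0.0994), cell division genes (TSO2, −1.21 ± 0.17, median 0.192, camera adjusted p = 0.27), flowering time genes (AGL20, −0.88 ± 0.19, camera adjusted p = 0.699) and Mediator subunits (MED10B, 0.53 ± 0.11, camera adjusted p = 0.699). No ethylene and jasmonate defence gene (median 0.826, camera adjusted p = 0.359; ERF1 at 2.47 ± 0.84), flavonoid gene (camera adjusted p = 0.875; DFR at −0.70 ± 0.47) or class III peroxidase (camera adjusted p = 0.685; PRX71 at −0.12 ± 0.55) passed. Without Col-0 control replicate 1, 8 lists passed, among them the defence (median 1.677), glucosinolate (0.422) and detoxification lists (0.396). The glucosinolate list also passed without Col-0 methyl viologen replicate 1 (0.394) or 3 (0.378) or med8 control replicate 3 (0.48), with the root marker covariate (0.354) and with 2 libraries left out (0.531). That covariate also let the detoxification (0.391) and expansin lists (0.34) pass, and leaving out 2 libraries the defence (1.134) and cell division lists (0.273). Detoxification genes passed without med8 control replicate 1 (0.412) or 2 (0.42), abscisic acid genes without med8 control replicate 2 (0.258), expansins without Col-0 control replicate 2 (0.399) or Col-0 methyl viologen replicate 2 (0.369), and cell division genes without med8 control replicate 3 (0.444). The camera adjusted p ran from 0.000388 to 0.854 for glucosinolates, 0.0164 to 0.854 for detoxification, 0.00249 to 0.854 for the defence list, 0.0455 to 0.854 for abscisic acid, 0.031 to 0.544 for expansins and 0.00102 to 0.904 for cell division.

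The interaction was called for 2885 genes (1296 positive, 1589 negative; 13.91% of those tested). Of these, 885 negative ones fell and 631 positive ones rose in med8 without passing in Col-0, 279 negative ones rose and 310 positive ones fell in Col-0 without passing in med8, and 198 rose in Col-0 and fell in med8 while 120 did the reverse. The count went to 1912 without Col-0 methyl viologen replicate 1, 1874 without med8 methyl viologen replicate 2 and 5097 with the root marker covariate. Of 24 lists 5 passed camera, 4 up and 1 down, and 0 with an estimated correlation. With 100 2-fold and 99 4-fold changes simulated, the interaction test recovered 54% and 87.9%, with 8.4% of calls false.

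**Figure D3:**
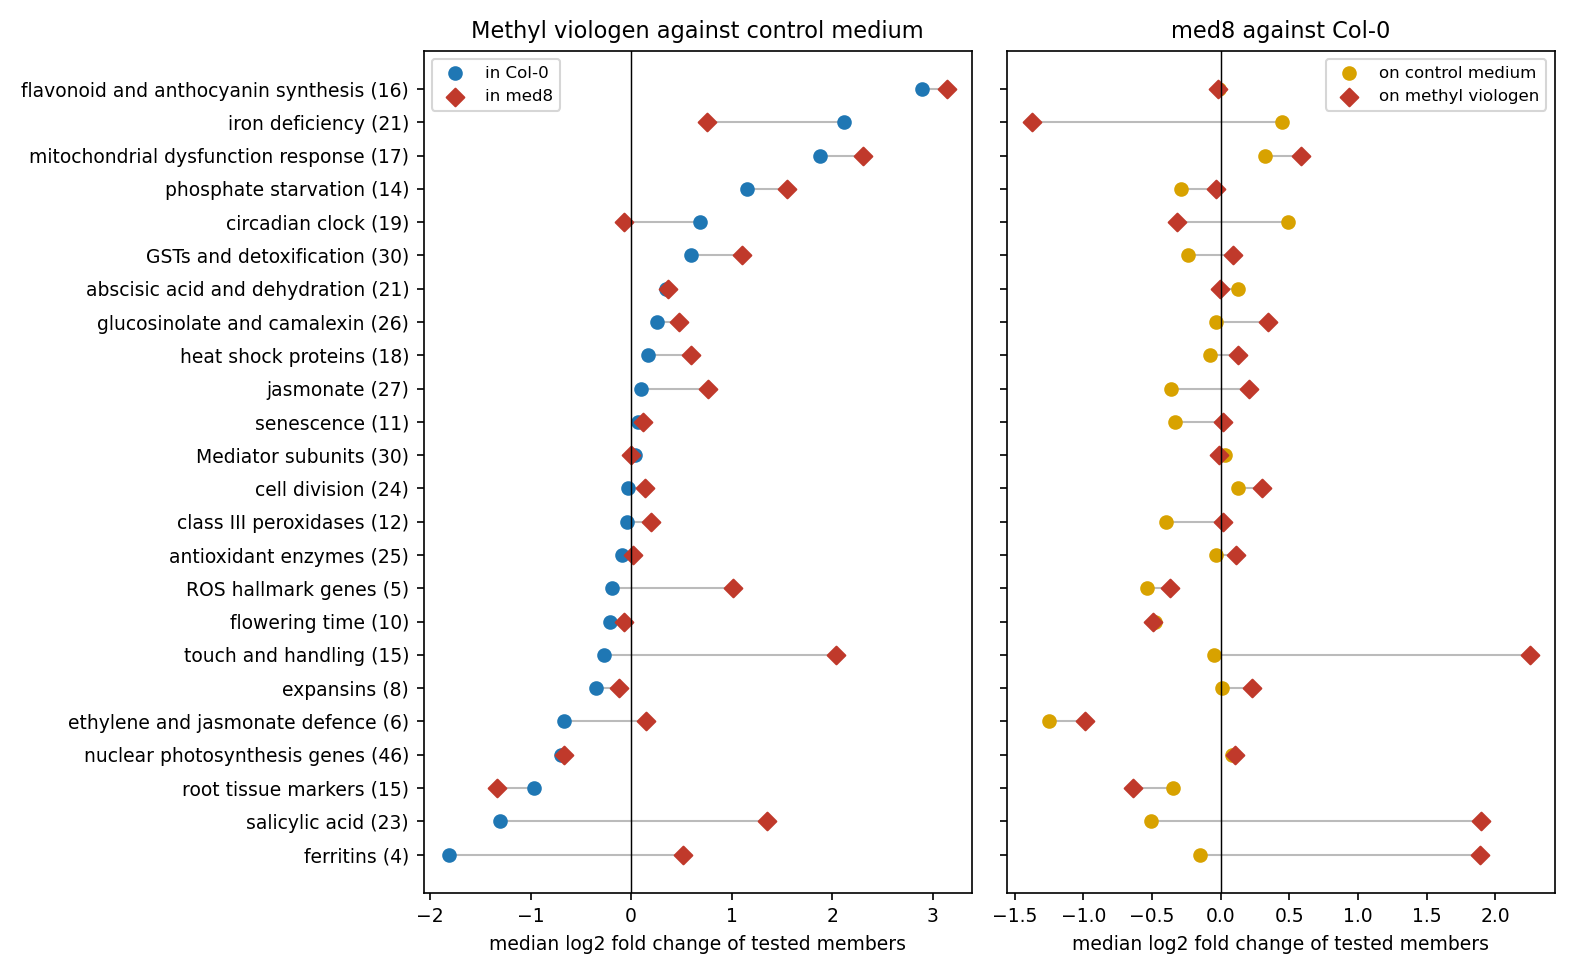
Median log2 fold change of the tested members of each gene list (number tested in brackets), with methyl viologen against control medium in each genotype (left) and med8 against Col-0 on each medium (right), and a grey line joining the 2 values of a list. The touch list stands at −0.273 in Col-0 and 2.039 in med8 on the left, and at −0.051 on control medium and 2.252 on methyl viologen on the right.

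Averaged over genotypes, methyl viologen changed 10114 genes (5200 higher, 4914 lower), and averaged over media, med8 differed in 3805 (1715 higher, 2090 lower). Across the 10114 genes that methyl viologen changed on average, the response in med8 exceeded that in Col-0 by a median of 0.1196 log2 units in the direction of the response, with median responses of 0.506 in med8 and 0.356 in Col-0. Methyl viologen responses of both genotypes correlated across genes with r = 0.483 (jackknife SE 0.129), and the genotype effects on both media with r = 0.092 (jackknife SE 0.126). Of those that differed between genotypes, 136 were higher and 243 lower in med8 on both media, 192 were higher on control medium and lower on methyl viologen, and 60 the reverse.

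The med8 effect on control medium and the methyl viologen effect in Col-0 shared 369 genes in the same direction (203 higher and 166 lower in both), with BHLH100, IMA2 and DTX3 among them, and 221 in opposite directions. Lists drawn independently would share 172.3 and 173. Both effects are measured against the same 3 Col-0 control libraries, which could not be split into sets of 2 or more, so part of the excess may come from the shared controls. Their covariance across genes was 0.0643, against 0.0297 (0.0267 to 0.0313) in 20 simulations without any change. These gave a correlation of 0.5 (0.466 to 0.519, here 0.219) and 0 shared genes by design, so neither tells the source. The same-direction count went to 175 without Col-0 control replicate 2, 135 without Col-0 control replicate 3, 237 without med8 control replicate 2 and 669 with the root marker covariate.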

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

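The tests of hour of harvest, handling and mislabelling below, both tests on the whole iron deficiency list, and the fits with a root marker covariate were chosen only after the results were seen.

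Several results stood out because the methyl viologen response differed between Col-0 and med8 in a test of the difference itself. These were the 2885 genes past the interaction threshold, the response size of 0.1196 log2 units, and the members past that threshold in the lists for jasmonate (8), salicylic acid (16), iron deficiency (15), ferritins (3), circadian clock (19) and touch (15). Single genes with the largest interactions stood out for the same reason, and their mean levels in med8 on methyl viologen were 1.35 CPM for PUM8, 8.71 for NAC061, 13.3 for CRK37, 7.21 for NAC090, 10.4 for PCR1, 0.3 for LEA7, 0.292 for AT5G66150, 2.14 for AT4G36700, 0.064 for AT4G08867 and 0.111 for AT4G15680. PUM8 had 0 counts in the med8 controls and AT5G66150 0 in the Col-0 controls. NAC061, NAC090 and CRK37 lost their calls without Col-0 control replicate 2 (interactions of 6.77, 5.45 and 5.49), PUM8 without Col-0 control replicate 1 (8.3) or with 2 libraries left out (8.32) and LEA7 without med8 control replicate 2 (−2.29). PCR1 lost its call in 6 fits, without Col-0 control replicate 2 (5.31), Col-0 methyl viologen replicate 1 (7.48) or 2 (7.61), med8 control replicate 1 (7.35) or 3 (7.37), or med8 methyl viologen replicate 2 (7.56), stood at 13.17 without med8 control replicate 2 and lost its call with the root marker covariate (8.23).

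Of 21 iron deficiency genes, 12 responded less to methyl viologen in med8 than in Col-0 and 3 more (median interaction −1.879; adjusted p = 0.324 with an estimated correlation in camera). A different hour of harvest remains a possible explanation: within groups the clock value and the mean level of the 12, chosen for their negative interaction, correlated with r = 0.56 over 12 libraries (exact within-group permutation p = 0.0856, two-sided; rho = 0.51, p = 0.202), and r was 0.39 without the 2 libraries farthest from the median. Against a different share of root tissue as the whole cause, the list median was −1.855 with the root marker covariate (camera adjusted p = 0.00166, range 1.3e-07 to 0.324). Against one library as the cause, the list passed camera in all 12 fits without a library, with a median of −1.586 at the weakest. An altered iron signal in med8 is a candidate biological explanation that these data cannot separate from the hour of harvest.

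Touch and handling genes were higher in med8 than in Col-0 on methyl viologen. All 3 libraries of that group lay above all other libraries in the mean level of these genes, so handling or hour at harvest of that group could explain the result, as could the genotype, and the design cannot tell these apart. One library does not explain it, since at least 15 members stayed higher in every fit without a library.

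Salicylic acid genes differed between the Col-0 control libraries. A mislabelled sample does not explain this: the lowest MED8 level of a Col-0 control was 18.87 CPM against 6.41 CPM at most in med8, and UPOX was 3.94 CPM at most in the Col-0 controls against at least 25.98 CPM on methyl viologen. A different share of root tissue remains possible, with a within-group r of 0.501 over 12 libraries (exact within-group permutation p = 0.0694, two-sided; rho = 0.548, p = 0.0841; r = 0.357 without the 2 farthest). A local infection of some plates is another possible cause that was not tested.

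Regrouping the same libraries tested whether chance could give results as large. For each pairwise comparison only 10 splits exist, too few for a share under 0.05. As many genes were reached in 1 of 10 splits, the real one, for methyl viologen in Col-0 (5969, others at most 0), methyl viologen in med8 (8931, 0), med8 on control medium (1200, 1) and med8 on methyl viologen (4906, 0). As many lists were reached in 5 of 10 (10, others at most 16), 1 of 10 (12, 11), 8 of 10 (8, 11) and 8 of 10 (6, 12). With 100 splits, chance can be excluded for the med8 average (1 of 100; 3805 against 2551) and the methyl viologen average (1 of 100; 10114 against 4416). Chance cannot be excluded for the interaction lists (80 of 100, 5 against 13) or the response size (6 of 100, 0.1196 against 0.1575). For the interaction genes 1 of 100 drawn splits reached 2885, the real one, and the next called 2799; apart from which genotype is named first, it exchanged only Col-0 control replicate 1 with med8 control replicate 2. Swapping all genotype labels on 1 medium, which was not drawn, turns the interaction into the med8 average and calls 3805, so these splits carry the genotype effect itself and whether chance can be excluded is left open for the interaction.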

How the results depend on the processing

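The root marker covariate and leaving out 2 libraries were chosen only after the data were seen; a fit without organelle genes was not run. Genes changed in med8 on control medium (1200) numbered 2497 with the root marker covariate, 1848 with 2 libraries left out and 1976 with DESeq2, for which the cause was not tested, and 143 when only the 2 groups were fitted, with fewer samples. The root marker covariate also gave 5097 interaction genes (2885) and 669 shared genes (369); the cause was not tested. With an estimated correlation 0 lists passed for methyl viologen in Col-0 or med8, for med8 on either medium or for the interaction. The cause was not tested. Lists for med8 on control medium (8) numbered 5 with a replicate block, 3 with the root marker covariate and 2 with fry, and interaction lists (5) numbered 8 with the root marker covariate and 8 with 2 libraries left out; the cause was not tested. With the root marker covariate HCYSTM1 turned to 0.42 for methyl viologen in Col-0, and TSO2, MCM3 and the cell division list to −0.26, −0.22 and −0.213 for methyl viologen in med8. The root marker list for med8 on control medium kept its sign in the median (−0.058) with 2 libraries left out while camera turned; the cause was not tested.

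Without 1 library each, genes changed numbered 402 to 1625 for med8 on control medium, 3211 to 6390 for med8 on methyl viologen and 1874 to 3332 for the interaction. Shared genes numbered 135 to 467, the response size was 0.082 to 0.149, lists for med8 on control medium numbered 3 to 12 and for the interaction 5 to 8, and the root marker list for med8 on control medium ran from −0.527 to 0.049. These fits have fewer samples. MED8 stayed between −1.93 and −1.77 on control medium. Of 364 gene-by-comparison results, ignoring signs of uncalled ones, RLE scaling kept 364, upper-quartile 361, DESeq2 359 and the replicate block 351. Leaving out 2 libraries kept 343, the root marker covariate 335 (3 reversed). Fits of only the 2 groups kept 253 of 294 (36 calls lost, 5 gained) and fits without 1 library 4106 of 4368 (251 lost, 11 gained). Of 18 pairs of same-numbered libraries 7 correlated above 0.1 (range −0.379 to 0.458). All 6 pairs of replicate 2 were positive, and 7 of 12 libraries correlated best with their own number, which is a hint from the data and not from the design. With the replicate block the glucosinolate list passed for med8 on methyl viologen (median 0.357, camera adjusted p = 0.0326, range 0.0188 to 0.81) and for the interaction (0.361, 0.0462, range 0.000388 to 0.854). For med8 on control medium detoxification, photosynthesis and root markers each moved to 0.0539; no other list call changed. Of 120 list results fry called 13 more and 13 fewer. Depth limits the folds of genes with 0 to 3 counts in a group.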

Other observations

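Outside the fixed lists, the glutaredoxin gene AT4G15690 had an interaction of −3.55 ± 0.35 (edgeR adjusted p = 7.27e-05). It averaged 1.63, 2.15, 1.9 and 0.21 CPM in Col-0 control, Col-0 methyl viologen, med8 control and med8 methyl viologen. Its neighbour AT4G15700 averaged 1.74, 1.39, 1.76 and 0.182 CPM (−2.92 ± 0.39, edgeR adjusted p = 0.000529). These genes were picked after their values were seen, and whether near-identical copies share reads was not tested.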
